A study of Mus musculus with 4 samples.

How the data were processed

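Total RNA was measured by RNA sequencing in 4 libraries from D2.OR cells grown for 7 days in 3D culture, 2 parental and 2 expressing BORG. Per the labels' protocols, cells were grown with Cultrex basement membrane extract, RNA was extracted with Trizol, and libraries were made with a stranded total RNA kit, which keeps RNAs without a poly(A) tail. The design text states biological duplicates and, on average, about 66 M paired-end reads of 100 nt per sample. The fragments assigned to genes came to 22.4 M on average, from 7.90 M in the shallowest library to 30.3 M in the deepest (a ratio of 3.84). The labels do not say whether the duplicates came from separate cultures on separate days, so p-values measure the spread between these libraries.

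The deposited table holds, per gene and library, estimated counts of fragments, scaled fragments as a signal, and FPKM, per the file headers. Per the submitters' processing notes the tools were FastQC, Trim Galore, TopHat and Cufflinks, with no version given, and the builds named were GRCm38, mm10 and mm8. The column names are those of a Cuffdiff read group table. The strand setting and annotation release are not given in the sources used here, so reads of a gene and its antisense partner may not be separated. The scaled fragments deposited by the authors are the estimated counts times 1 factor per library, and 1 further column of scaled fragments was left unused because it repeats those values. The FPKM deposited by the authors are fragments per kilobase of transcript and per M fragments.

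The table names its conditions BORG and Empty. Empty was taken as parental, being the only condition that is not BORG, and the table's replicate numbers, which start at 0, were read as replicates 1 and 2. The second reading decides which replicate number each library's values, each left-out library and the pairing of libraries carry; it does not affect the groups or the test of BORG-expressing against parental cells. Whether the cells named Empty carried an empty vector was not settled here, so an effect of carrying a vector may not be separated from that of BORG. Identifiers were matched to symbols with GENCODE M21 names: 48051 of 48432 had a symbol and 381 did not. 23572 identifiers had no fragment in any library. Coordinates and overlaps come from GENCODE M21 on GRCm38. Of 129 named genes 23 overlap a gene on the same strand and 46 a gene on the opposite strand, so that their counts are uncertain to the extent that reads were not split; Cth is among the first, and Csf2, Cbln1, Rab39b, Pdgfb, Cdkn1a, Gadd45a, Trim28 and Fdft1 are among the second. Members of families of near-identical genes, such as histones, ribosomal proteins, glutathione transferases, Oas and H2-T genes, can share reads and are uncertain for the same reason.

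The expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, quasi-likelihood F test, Benjamini-Hochberg over all 15116 genes tested, two-sided, threshold 0.05). The biological coefficient of variation was 0.168 and the prior degrees of freedom were 4.29. Standard errors are the log2 fold change divided by the square root of F. Levels are CPM with TMM factors, given as mean ± SD of 2 libraries. A fold against a group with 0 counts uses a floor of 3 counts over the group, and ratios on 1 to 3 counts have an exact 95% interval. Replicates were not copies of each other: the chi-square per degree of freedom between replicates was 81.2 (parental) and 21.4 (BORG-expressing), over genes with at least 20 fragments.

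Before the data were examined, 38 gene lists, the tests, the alternatives and the rule for named genes were fixed. The plan named limma on log2(FPKM + 1) with trend and robust variance for FPKM, or edgeR for counts. It did not say which to use for data that hold both, and edgeR was taken as the main test. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, Benjamini-Hochberg over lists), beside camera with an estimated correlation and fry. Named genes were the 10 with the highest and the 10 with the lowest log2 fold change among genes that passed, with both libraries of a group on the same side and a mean of at least 1 FPKM, leaving out clone names, predicted genes, microRNAs, small nucleolar RNAs and pseudogenes. Up to 4 members with the smallest p were added for each list that passed or had at least 3 members past the gene test, and Trim28, Cdkn1a, Gadd45a and BORG in any case. Not every gene selected by this rule is reported here. Dhcr7, Atf4, Ddit3, Hspa5, Hsp90b1, Calr, Pdia4, Slc7a11, Hmox1, Slc2a1, Hk2, Mki67, Rpa1, Ccnb2, Aurkb, Gsta1, Gclc, Oas2, Oas3, Bst2, Malat1, Gm26917 and AY036118 lie outside that rule and were chosen after their values were seen. So were Acss2, Scd2, Dbp, Per3, Ciart, Arntl, Neat1, Trp53, Phgdh, Slc1a5, Wars, Pcna, Mcm4 and Mcm6, and the lists described as made after seeing the data.

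The alternatives were the replicate block, leaving out each library, another filter, other scalings, quantile normalization, limma on log2(FPKM + 1) and with pseudocounts of 0.1 and 0.5, rows of 1 symbol summed, DESeq2 1.42.0, and, chosen after seeing the data, GC and length correction, thinning to 7900769 fragments, leaving out Ahnak and Gm26917, a crossed block and a robust prior. GC content and length were known for 99.6% of tested genes.

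The test was run on simulated data under 2 dispersion models, the second added after the result of the first was seen. The models drew 200 changed genes on the real means and library sizes of the comparison of BORG-expressing with parental cells. With each gene's own dispersion estimate (14748 genes fitted), 15.4%, 66.1% and 69.2% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, and 21 of 108 calls (19.4%) were false. With dispersions spread around the trend (14780 genes fitted, the added model), 1.45%, 29.7% and 72.3% were recovered and 7 of 75 calls (9.33%) were false. The false share was thus above the nominal level of 0.05 in both, on few calls, while 4.92% and 4.79% of unchanged genes had an unadjusted p under 0.05. Far fewer genes were changed in the simulation than passed in the data (6220 of 15116). The false share and the recovery depend on that fraction, so they do not carry over to the real calls. The recovery first required at 4-fold was not reached under either model, and that requirement was replaced by bounds on the p-values of unchanged genes, on the error of the fold change and on the raised list. A list of 25 genes raised 1.5-fold was called and 0 of 30 unchanged lists were, in each model. The simulated genes were drawn independently of each other, so this does not check the preset correlation used for the real lists.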

Results

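RNA was sequenced from D2.OR cells, a mouse mammary line derived from pre-malignant hyperplastic alveolar cells, kept for 7 days in 3D culture with a basement membrane extract. Parental cells (2 libraries) were compared with cells expressing BORG (2 libraries), a long non-coding RNA. The parental libraries held 24176438 and 30322679 fragments assigned to genes. The BORG-expressing libraries held 7900767 and 27131662. Replicates correlated across genes with Pearson's r of 0.982 (parental) and 0.973 (BORG-expressing), against 0.910 to 0.928 between groups, where genes are not independent replicates. The first principal component held 74.4% of the variance and the second 18.9%.

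The first question was which genes differ when BORG is expressed. Of 15116 genes tested, 6220 (41.1%) passed an adjusted p of 0.05, with 3001 higher and 3219 lower in BORG-expressing cells. Fewer passed in the 4 limma fits to FPKM (2391 to 3379 of 12747 genes tested), and with the replicate block 1986 were higher and 2204 lower. More passed with a crossed block, chosen after seeing the data (4619 higher, 4700 lower). A change of at least 2-fold was found for 1449 genes that rose and 1516 that fell. Among the genes that fell most were Cth and Fgf21. Cth, the enzyme that makes cysteine from cystathionine, fell by 5.52 ± 0.14 on the log2 scale (SE, edgeR adjusted p = 6.22e-05), from 153 ± 3.66 to 3.29 ± 0.190 CPM (SD, n = 2 per group). Fgf21, a stress-responsive hormone, fell by 6.29 ± 0.27 (adjusted p = 7.17e-05). Nqo1, a quinone reductase, rose by 3.32 ± 0.11 (adjusted p = 6.22e-05, 64.7 ± 3.30 against 649 ± 32.7 CPM). The cytokine genes Csf2, Ccl20 and Ccl4 also fell.

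Ypel4 rose by 5.70 ± 0.23 on the log2 scale (adjusted p = 7.17e-05). Cyp1a1, a xenobiotic-metabolising cytochrome P450, rose by 5.49 ± 0.29 (adjusted p = 1.1e-04), and Pdgfb, a growth factor chain, rose by 5.00 ± 0.36 (adjusted p = 2.5e-04). Tmem182, Gja4 (a gap junction protein), Bmf (a pro-apoptotic BH3-only protein) and Cbln1 rose by between 4.51 and 4.99. Ghrh, the growth hormone releasing hormone gene, had no fragment in either parental library and 76 in the BORG-expressing libraries, which is at least 38.7-fold higher against a floor of 3 counts over the group. Pagr1a rose by 7.24 ± 0.58 (adjusted p = 3.5e-04), but it overlaps Pagr1b on the same strand, its value is uncertain, and it did not pass in limma on log2(FPKM + 0.1) (adjusted p = 0.0785).

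In the other direction, the small GTPase gene Rab39b fell by 6.38 ± 0.23 on the log2 scale (71.4 ± 12.9 against 0.861 ± 0.0324 CPM, adjusted p = 6.41e-05). Atp2a3, a calcium pump of the endoplasmic reticulum, fell by 5.80 ± 0.27 (adjusted p = 8.22e-05). Pla2g2e, a secreted phospholipase, fell by 5.72 ± 0.40 (adjusted p = 2.3e-04). Cdsn, which encodes corneodesmosin, fell by 5.60 ± 0.20 (adjusted p = 6.41e-05). Ccl4, a chemokine gene, fell by 5.16 ± 0.39 (adjusted p = 2.74e-04). Csf2, encoding GM-CSF, had 439 parental and 2 BORG-expressing counts, a ratio of 144 with a 95% counting interval of 39.5 to 1189. Ccl20 had 167 and 2 counts, a ratio of 54.6 (14.9 to 455). Rn7s6, a structural RNA of the signal recognition particle, had 98 parental counts and 0 in the BORG-expressing libraries, at least 21.4-fold lower against the same floor; it overlaps a predicted gene on the same strand and is uncertain. Intervals and floors cover counting error only.

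Cth lies on chromosome 3 at 157894248 to 157925077, Rab39b on chromosome X at 75572046 to 75578231, Nqo1 on chromosome 8 at 107388225 to 107403206 and Asns on chromosome 6 at 7675169 to 7693254, all in GRCm38 coordinates of the annotation used here. BORG itself (chromosome 15, 38713483 to 38728516) had 0 matching identifiers in the table, so its level was not analysed here and the labels were not checked against it. Ahnak, a very large scaffold protein gene, was listed at 0 in both parental libraries and at 109371 and 295346 fragments in the BORG-expressing libraries. No fold is given for Ahnak, since the 13 mitochondrial messenger RNAs and Malat1, which mammalian cells make in quantity, were listed at 0 in all 4 libraries too.

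**Figure D1:**
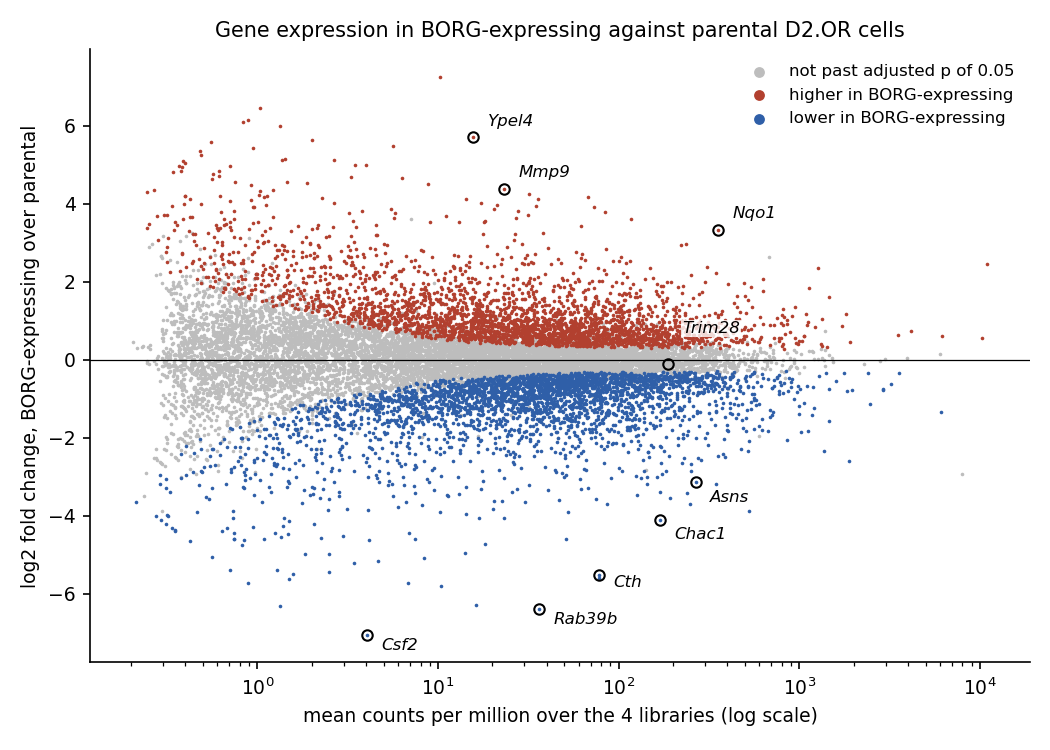
Log2 fold change of BORG-expressing over parental cells (vertical axis) against mean CPM over the 4 libraries (horizontal axis, log scale), 1 point per tested gene, with circles around 9 labelled genes. The 3001 genes higher and 3219 genes lower at an adjusted p of 0.05 are coloured, except that the 40 tested genes at 0 in both libraries of a group are left out because their fold has no fixed value.

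Cdkn1a, Gadd45a and Trim28 were examined whatever their change. Cdkn1a, which encodes the cell cycle inhibitor p21, fell by 1.91 ± 0.20 on the log2 scale (58.0 ± 7.95 against 15.0 ± 3.89 CPM, adjusted p = 8.91e-04). Gadd45a, a growth arrest and DNA damage gene, fell by 3.05 ± 0.14 (109 ± 13.7 against 13.2 ± 0.318 CPM, adjusted p = 8.22e-05). Trim28, a chromatin co-repressor, differed by -0.12 ± 0.12 (195 ± 5.76 against 179 ± 24.8 CPM, adjusted p = 0.470), which is within the spread between replicates. After GC and length correction Trim28 was lower by the test (-0.32, adjusted p = 0.0200, or 0.0708 with the replicate block), and without BORG-expressing replicate 1 its value was 0.00224 (adjusted p = 0.992). Of 20 tested genes of TRIM28 and its partners, 6 rose and 4 fell (6 and 4 adjusted over the list alone), with Atf7ip up by 1.27 ± 0.10 (adjusted p = 3.46e-04). That list did not pass (adjusted p = 0.746).

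The second question was which gene lists, fixed in advance, differed together. Of 36 lists tested, 7 passed the list test at an adjusted p of 0.05, 3 of them higher in BORG-expressing cells (cholesterol synthesis, NRF2 and oxidative stress, hypoxia and glycolysis) and 4 lower (unfolded protein response, DNA replication and repair, type I interferon response, cell cycle and mitosis). None of the 7 held with an estimated correlation between genes, where 0 lists passed (1 at an unadjusted p under 0.05) and the adjusted p was 0.663 for each of these 7. Gene correlation alone does not account for this loss. The estimate was below the preset 0.01 for the NRF2 (-0.0103) and interferon (-0.0300) lists. For the others it ran from 0.0119 (hypoxia and glycolysis) to 0.146 (DNA replication and repair). That form of the test also rests on the few residual degrees of freedom of 4 libraries, which makes it harder for a list to pass. A low p remained possible: a list of amino acid response genes made after seeing the data reached an unadjusted p of 0.00966 in it. The few degrees of freedom therefore do not by themselves explain why the 7 lists failed. The rotation test fry, which asks whether a list's genes move one way without comparing them with other genes, passed 25 lists.

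Cholesterol synthesis genes rose together. Of 23 tested members 18 rose and 1 fell (18 and 1 adjusted over the list alone), with a median log2 fold change of 1.34 (list test adjusted p = 1.06e-08, adjusted p = 0.663 with an estimated correlation). Stard4, a sterol carrier, rose by 2.57 ± 0.11 (adjusted p = 7.17e-05), Acat2 by 2.62 ± 0.14 (adjusted p = 1.13e-04), the mevalonate pathway enzyme gene Pmvk by 2.30 ± 0.11 (adjusted p = 8.22e-05) and the squalene synthase gene Fdft1 by 2.07 ± 0.11 (adjusted p = 1.1e-04). Dhcr7 fell by 0.90 ± 0.14 (adjusted p = 0.00387).

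The unfolded protein response list fell, with 14 of 23 tested members lower, 0 higher and 9 not past the test (14 and 0 adjusted over the list alone). Its median was -0.54 (list test adjusted p = 4.99e-06, adjusted p = 0.663 with an estimated correlation). The members with the smallest p were Chac1, a glutathione-degrading enzyme (fell by 4.11 ± 0.16, adjusted p = 6.47e-05), Asns, asparagine synthetase (fell by 3.14 ± 0.10, adjusted p = 6.22e-05), the pseudokinase gene Trib3 (fell by 2.98 ± 0.11, adjusted p = 6.47e-05) and the phosphatase subunit gene Ppp1r15a (fell by 2.50 ± 0.11, adjusted p = 7.46e-05). Atf4, the transcription factor of the integrated stress response, fell by 1.83 ± 0.10 (adjusted p = 1.08e-04) and its partner gene Ddit3 by 1.71 ± 0.11 (adjusted p = 1.77e-04). Among the chaperones of the endoplasmic reticulum, Hspa5 fell by 1.13 ± 0.14 (adjusted p = 0.0014), while Hsp90b1 (0.01 ± 0.18), Calr (-0.06 ± 0.09) and Pdia4 (-0.12 ± 0.10) did not pass.

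Genes of DNA replication and repair fell. Of 28 tested members 19 fell and 1 rose (20 and 1 adjusted over the list alone), with a median of -0.93 (list test adjusted p = 5.18e-05, adjusted p = 0.663 with an estimated correlation). The member that rose was Rpa1 (0.53 ± 0.12). The replicative helicase gene Mcm3 fell by 1.56 ± 0.14 (adjusted p = 4.42e-04), the polymerase gene Pola1 by 1.56 ± 0.18 (adjusted p = 0.00129) and Brca2 by 1.27 ± 0.16 (adjusted p = 0.00162). With only genes of at least 5 FPKM on average the list no longer passed (median -0.57, adjusted p = 0.0916).

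Genes of the cell cycle and mitosis were lower as a list, with 11 of 28 members that fell and 3 that rose (13 and 3 adjusted over the list alone), a median of -0.37 and a list test adjusted p of 0.0412 (adjusted p = 0.663 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit, fell by 1.86 ± 0.13 (adjusted p = 2.48e-04), the kinesin gene Kif11 by 1.33 ± 0.15 (adjusted p = 0.00107) and the cyclin gene Ccnd1 by 0.80 ± 0.09 (adjusted p = 0.00104), while E2f1 rose by 1.13 ± 0.17 (adjusted p = 0.00294), Ccnb2 by 0.69 ± 0.15 and Aurkb by 0.64 ± 0.18. The proliferation marker gene Mki67 did not pass (-0.12 ± 0.13, adjusted p = 0.478). Without parental replicate 2 the list's adjusted p was 0.0595 and without BORG-expressing replicate 2 it was 0.159. The call was also lost with at least 5 FPKM (0.112), quantile normalization (0.0570) and GC and length correction (0.0645, or 0.0583 with the replicate block).

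NRF2 targets and oxidative stress genes were higher as a list, with 16 of 27 members that rose and 4 that fell (17 and 4 adjusted over the list alone) and a median of 0.58 (list test adjusted p = 4.87e-04, adjusted p = 0.663 with an estimated correlation). Besides Nqo1, the glutathione transferase gene Gsta2 rose by 2.86 ± 0.14 (adjusted p = 8.22e-05), Cat, which encodes catalase, by 1.89 ± 0.11 (adjusted p = 1.17e-04) and the glutathione reductase gene Gsr by 1.45 ± 0.10 (adjusted p = 2.36e-04). The cystine transporter gene Slc7a11 fell by 1.34 ± 0.15 (adjusted p = 9.97e-04) and Hmox1, heme oxygenase, by 0.90 ± 0.12 (adjusted p = 0.00236). Gsta1 fell by 0.83 ± 0.15 and Gclc, of glutathione synthesis, fell by 0.39 ± 0.11.

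Hypoxia and glycolysis genes were higher as a list. Of 28 members 15 rose and 4 fell (16 and 4 adjusted over the list alone), with a median of 0.63 (list test adjusted p = 0.00265, adjusted p = 0.663 with an estimated correlation). The carbonic anhydrase genes Car9 and Car12 rose by 1.88 ± 0.10 (adjusted p = 1.16e-04) and 1.75 ± 0.09 (adjusted p = 9.92e-05). The 4 members that fell were Vegfa, an angiogenic growth factor gene (by 1.40 ± 0.10, adjusted p = 2.17e-04), Ndrg1 (by 1.14 ± 0.09, adjusted p = 3.37e-04), the glucose transporter gene Slc2a1 (by 0.82 ± 0.13, adjusted p = 0.00423) and the hexokinase gene Hk2 (by 0.72 ± 0.10, adjusted p = 0.00257).

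Type I interferon response genes were lower as a list, with 15 of 30 members that fell and 4 that rose (15 and 6 adjusted over the list alone) and a median of -0.43 (list test adjusted p = 0.0412, adjusted p = 0.663 with an estimated correlation). Oasl1 fell by 1.55 ± 0.11 (adjusted p = 2.56e-04), the RNA sensor gene Ifih1 by 1.59 ± 0.12 (adjusted p = 2.69e-04) and Rsad2, which encodes viperin, by 1.44 ± 0.11 (adjusted p = 3.39e-04), while Irf7, an interferon regulatory factor, rose by 1.36 ± 0.10 (adjusted p = 2.98e-04), as did Oas3 (1.03 ± 0.12), Oas2 (0.99 ± 0.15) and Bst2 (0.87 ± 0.16). The list lost its call without parental replicate 2 (adjusted p = 0.0595) and without BORG-expressing replicate 2 (0.0686), with at least 5 FPKM (0.0916), quantile normalization (0.0570) and GC and length correction (0.111, or 0.105 with the replicate block). It was lost also in each of the 4 fits to FPKM, with an adjusted p from 0.0760 to 0.0803.

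**Figure D2:**
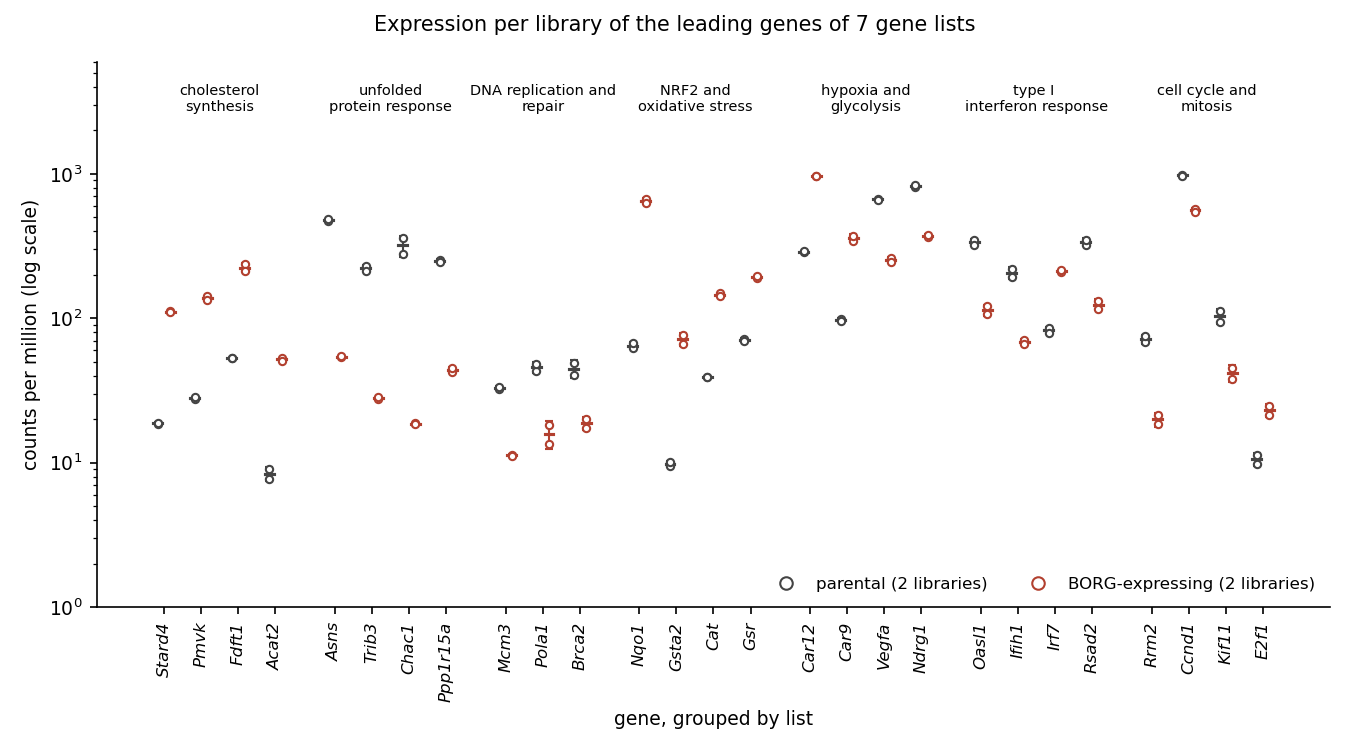
CPM (vertical axis, log scale) of up to 4 members with the smallest p in each of the 7 lists that passed the list test (horizontal axis), with open circles for the 2 libraries of each group, a bar for the mean and whiskers for the SD. In each of these genes both BORG-expressing libraries lie on the same side of both parental libraries, as for Nqo1 (64.7 against 649) and Asns (479 against 54.3).

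Lists that did not pass still held genes that changed, as did 41.1% of all tested genes. A count near that share, here and in the paragraphs below, says little about a list. Of 27 growth factor and MAPK feedback genes 14 fell and 6 rose (15 and 7 adjusted over the list alone, list test adjusted p = 0.0515), among them the EGFR ligand gene Areg (-2.86 ± 0.16), Egr1 (-2.84 ± 0.15), Fos (-2.27 ± 0.15) and the phosphatase gene Dusp6 (-1.81 ± 0.11). Of 16 antigen presentation genes 7 rose and 2 fell (7 and 2 adjusted over the list alone, list test adjusted p = 0.0515), among them B2m, which rose by 1.15 ± 0.10 (adjusted p = 4.94e-04). Of 25 p53 and growth arrest targets 11 fell and 6 rose (13 and 7 adjusted over the list alone, list test adjusted p = 0.0999), with Plk3 (-2.20 ± 0.14) and Sesn2 (-2.80 ± 0.16) lower. The NF-kB targets held 11 that fell and 6 that rose of 30 (11 and 6 adjusted over the list alone, list test adjusted p = 0.248), with Csf1 lower (-2.36 ± 0.11) and Il1a higher (2.58 ± 0.14).

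Matrix and adhesion genes went both ways. Mmp9, a gelatinase gene, rose by 4.37 ± 0.24 (2.16 ± 0.629 against 44.3 ± 5.27 CPM, adjusted p = 1.11e-04), while the inhibitor gene Timp1 fell by 2.04 ± 0.10 (adjusted p = 8.69e-05) and Timp3 rose by 1.66 ± 0.13 (adjusted p = 3.35e-04). Of 25 matrix proteases and inhibitors 10 rose and 6 fell (11 and 6 adjusted over the list alone, list test adjusted p = 0.248). Of 17 integrin genes 7 rose and 4 fell (8 and 4 adjusted over the list alone, list test adjusted p = 0.447), with Itgb3 higher (2.0 ± 0.10) and Itgb7 lower (-3.43 ± 0.24). Of 19 mesenchymal genes 4 rose and 6 fell (6 and 6 adjusted over the list alone, list test adjusted p = 0.970). The transcription factor gene Snai2 fell by 3.91 ± 0.22 (adjusted p = 1.21e-04) and the fibronectin gene Fn1 fell by 1.17 ± 0.11 (adjusted p = 6.26e-04). The vimentin gene Vim rose by 0.73 ± 0.10 (adjusted p = 0.00204), a call lost in the 4 fits to FPKM (adjusted p from 0.0623 to 0.155). Of 28 epithelial adhesion genes 10 rose and 5 fell (11 and 5 adjusted over the list alone, list test adjusted p = 0.248). The desmoplakin gene Dsp rose by 1.96 ± 0.11 (adjusted p = 1.14e-04).

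Genes of stem and progenitor cells, mammary lineages and dormancy also split. Myc fell by 2.37 ± 0.16 (adjusted p = 2.06e-04) and Klf4 by 1.84 ± 0.13 (adjusted p = 2.46e-04), with 10 of 21 stem and progenitor genes higher and 7 lower (11 and 7 adjusted over the list alone, list test adjusted p = 0.447). Of 15 metastatic dormancy genes 8 rose and 5 fell (8 and 6 adjusted over the list alone, list test adjusted p = 0.341), with the matrix protein gene Thbs1 higher by 1.75 ± 0.10 and Tgfb2 higher by 1.88 ± 0.14. Krt14 rose by 1.35 ± 0.09 and Krt6a fell by 1.93 ± 0.12 among 14 basal and myoepithelial genes, of which 6 rose and 4 fell (6 and 5 adjusted over the list alone, list test adjusted p = 0.478). Of 13 luminal genes 6 rose and 3 fell (6 and 3 adjusted over the list alone, list test adjusted p = 0.552).

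The 20 immediate early genes held 8 that fell and 3 that rose (8 and 3 adjusted over the list alone, list test adjusted p = 0.248), with Atf3 lower (-2.40 ± 0.12). Of 12 WNT targets 7 fell and 4 rose (7 and 4 adjusted over the list alone, list test adjusted p = 0.447), with Wnt7b lower (-3.33 ± 0.16). The 16 BMP targets held 7 higher and 4 lower (8 and 4 adjusted over the list alone, list test adjusted p = 0.248), with Smad6 higher by 1.86 ± 0.22. Of 12 multidrug transporters 6 rose and 1 fell (7 and 2 adjusted over the list alone, list test adjusted p = 0.248), and of 16 pro-apoptotic genes 7 rose and 5 fell (8 and 7 adjusted over the list alone, list test adjusted p = 0.478), with Bcl2l11 higher by 1.27 ± 0.11. Of 23 chemokines and cytokines 9 fell and 6 rose (9 and 8 adjusted over the list alone, list test adjusted p = 0.644), with Cxcl10 lower (-2.71 ± 0.12) and Cxcl5 higher (1.35 ± 0.09). Cxcl5 did not pass in 3 of the 4 fits to FPKM (adjusted p from 0.0557 to 0.0662).

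The remaining lists lay at a list test adjusted p of 0.341 or more. Of 30 ribosomal protein genes 4 rose and 2 fell (4 and 2 adjusted over the list alone, adjusted p = 0.341), of 28 matrix and basement membrane genes 9 rose and 7 fell (9 and 9, adjusted p = 0.831), of 17 YAP and TEAD targets 4 rose and 5 fell (4 and 5, adjusted p = 0.831) and of 11 imprinted genes 2 rose and 1 fell (2 and 1, adjusted p = 0.880). Of 22 TGF-beta targets 5 rose and 8 fell (5 and 8, adjusted p = 0.880), of 9 anti-apoptotic genes 1 rose and 2 fell (1 and 2, adjusted p = 0.990) and of 5 milk and alveolar genes 1 rose and 1 fell (1 and 2, adjusted p = 0.901). Markers of other cell types gave 0 rising and 2 falling of 5 fibroblast genes (0 and 2, adjusted p = 0.831), 2 and 3 of 7 endothelial genes (2 and 3, adjusted p = 0.880) and 1 and 1 of 5 leukocyte genes (1 and 1, adjusted p = 0.990). In the TGF-beta, fibroblast, milk, mesenchymal and anti-apoptotic lists the median was above 0 while the test pointed down, with a mean below 0 in the milk and anti-apoptotic lists. In the TRIM28, ribosomal protein, imprinted and leukocyte lists the median was above 0 and the test pointed up while the mean was below 0. Adipocyte and muscle markers had 4 tested members and mitochondrially encoded genes 0, under the minimum of 5.

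**Figure D3:**
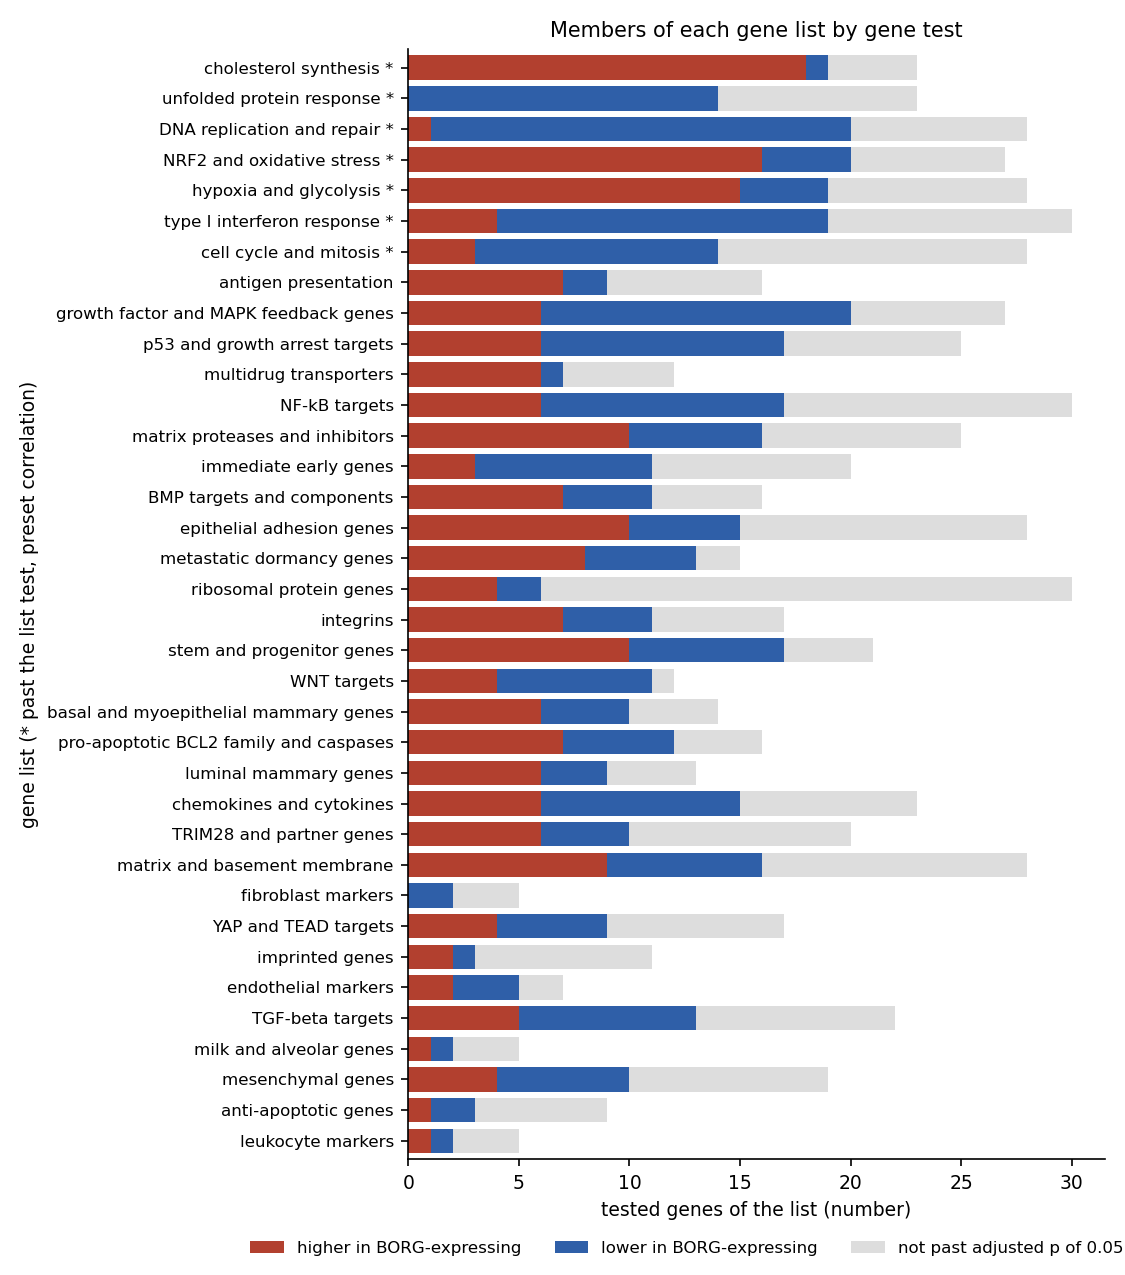
Number of tested genes per list (horizontal axis) that were higher, lower or not past an adjusted p of 0.05 in BORG-expressing against parental cells, for 36 lists (vertical axis, ordered by list test p, with a star for the 7 that passed). Cholesterol synthesis had 18 members higher and 1 lower of 23, and the unfolded protein response 0 higher and 14 lower of 23.

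Small non-polyadenylated RNAs separated the libraries in another way than the groups did. Over 24 such RNAs, a list chosen after seeing the data, the median level was 7.01 log2 CPM in parental replicate 1 and 6.97 in BORG-expressing replicate 2, against 5.57 in parental replicate 2 and 5.87 in BORG-expressing replicate 1. AY036118, counted here as rRNA-like, had 670543 and 99245 fragments in the first pair and 1780 and 687 in the second. As shares of each library these were 2.77% and 0.366%, and 0.00587% and 0.00870%. Its level therefore also differed within the first pair. Each pair has 1 library per group. Within the first and the second pair the median log2 difference was 1.34 and 1.37 for cholesterol synthesis, 0.85 and 0.60 for NRF2 and oxidative stress, and 0.64 and 0.57 for hypoxia and glycolysis. It was -0.61 and -0.49 for the unfolded protein response, -0.82 and -0.88 for DNA replication and repair, -0.42 and -0.44 for the interferon response and -0.42 and -0.33 for cell cycle and mitosis.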

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

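The GC and length correction, thinning, crossed block, robust prior and the fit without Ahnak and Gm26917 were chosen after the data were seen. Limma on log2(FPKM + 1) with trend and robust variance was the plan's test for FPKM, but was not planned as an alternative to edgeR. The other settings were planned. Between 4743 and 5905 genes passed when 1 library was left out (2198 to 2785 higher, 2545 to 3120 lower), and 6 to 9 lists, the lone library being assumed to vary like the other group. The same-numbered libraries share only a number (their deviations from the group means correlated at -0.44): with the replicate block 4190 genes passed (1986 higher, 2204 lower) and 9 lists. With the crossed replicate block (parental 1 with BORG-expressing 2, parental 2 with BORG-expressing 1) 9319 passed (4619 higher, 4700 lower). With limma on log2(FPKM + 0.1) 3379 genes passed (1509 higher, 1870 lower), on log2(FPKM + 0.5) 3295 (1467, 1828), on log2(FPKM + 1) 3321 (1479, 1842) and without trend and robust variance 2391 (1036, 1355); 12747 genes were tested there against 15116, and the cause of the rest of the difference was not tested. DESeq2 called 5852 genes, GC and length correction 7501 and thinning 5623. Camera with an estimated correlation passed 0 lists (1 at an unadjusted p under 0.05), fry 25. Trim28 ranged from -0.27 to 0.00224 on the log2 scale when 1 library was left out (the latter without BORG-expressing replicate 1), past the test in none of those fits. Of 2791 values for 128 named genes under alternatives, 2707 kept direction and side of the threshold, 82 fell short of it, 1 newly passed (Trim28 after GC and length correction, -0.32) and 1, Trim28, reversed. Flt1, Rps14, Chd4 and Gnas lost their call without either parental library, and with the replicate block together with Dnmt1. The share of calls that were higher was 48.2%, or 53.6% with upper quartile scaling. The authors' own q values were not run because the table used here holds none, and DESeq2 gave no list test. The library of 7.90 M fragments limits genes at low counts.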

Other observations

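All tests below were chosen after the data were seen, of which the thinning and the GC and length correction of the amino acid genes had their bounds set before their own results were seen, and 3 others replaced first versions: the non-polyadenylated RNA test, the depth test of DNA replication and the window test without gene families.

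Genes of fatty acid synthesis, a list made after seeing the data, rose together with those of cholesterol synthesis: 10 of 17 rose and 2 fell (12 and 2 adjusted over the list alone), with a median log2 fold change of 0.67 (adjusted p = 8.74e-04, and adjusted p = 0.216 with an estimated correlation). Acss2, acetyl-CoA synthetase, rose by 2.53 ± 0.12 and the desaturase gene Scd2 by 1.83 ± 0.10. Genes of the circadian clock split: of 18 members 5 rose and 6 fell (adjusted p = 0.816), with Dbp higher by 3.53 ± 0.24 and Per3 by 2.48 ± 0.15, and with Ciart (-3.90 ± 0.13) and Arntl (-2.47 ± 0.12) lower. Of 29 lysosomal genes 8 rose and 7 fell (adjusted p = 0.816). The nuclear long non-coding RNA Neat1 rose by 2.46 ± 0.09 and Trp53 rose by 2.36 ± 0.18, whereas the p53 target Cdkn1a fell by 1.91 ± 0.20. Cdkn1a does not stand for all such targets: of 25 p53 and growth arrest targets 11 fell and 6 rose.

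Outside the fixed lists, 29 of 33 textbook members of the amino acid response, gathered after a fall of such genes had been seen, fell and 0 rose (median log2 fold change -2.0, adjusted p = 1.11e-17), such as Phgdh (fell by 3.03 ± 0.14), Slc1a5 (fell by 3.00 ± 0.11) and Wars (fell by 2.86 ± 0.11). Since that fall led to the list, the list's p-values are descriptive and are no independent test of the response. With an estimated correlation the call depended on which lists made after seeing the data were adjusted together: adjusted p = 0.0676 over the 7 kept, adjusted p = 0.0386 with an overlapping list as the eighth, and p = 0.00966 unadjusted. Correcting for GC content and length left 29 of 29 calls (100%), which argues against these as the whole origin. That correction kept 6084 of all 6220 calls in the same direction, so the result is not particular to these genes. Thinning every library to the shallowest also left 29 of 29. It could hardly remove calls at such levels, so it decides little about depth. The list's median level was 8.39 and 8.42 log2 CPM in the parental and 6.39 and 6.43 in the BORG-expressing libraries. Chaperone and degradation genes of the endoplasmic reticulum also leaned down, with 6 of 21 that fell and 1 that rose (median -0.13, camera adjusted p = 0.0987, fry adjusted p = 0.0258). Their median lay 1.88 ± 0.17 above that of the amino acid genes (SE, bootstrap over genes, which leaves out the spread between libraries). The 2 lists can respond to the same stress by different amounts, so this difference does not decide whether stress of that compartment was the origin. A lower activity of the ATF4-dependent amino acid response in BORG-expressing cells may account for the pattern, while nutrient supply and cell density were not tested.

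The fall of DNA replication genes went with a fall of replication-dependent histone genes, of which 31 of 49 fell and 0 rose (35 and 1 adjusted over the list alone, median -1.48, adjusted p = 7.52e-09, but adjusted p = 0.652 with an estimated correlation and fry adjusted p = 0.128; family members share reads). A lower yield of non-polyadenylated RNA is argued against by the 2 pairs of libraries with like levels of such RNAs. Beyond the difference in those RNAs, histones differed by -2.04 log2 units in the first pair and -1.74 in the second. This comparison replaced a first test on the median of those RNAs (0.41), since their levels differed between replicates. Low depth of BORG-expressing replicate 1 is argued against too, since without it the DNA replication list had a median of -0.86 (adjusted p = 4.98e-06 with the preset correlation, while over all libraries adjusted p = 0.663 with an estimated correlation), a test that replaced thinning, which kept 16 of 19 calls (84.2%) and decided neither way. Fewer cells in S phase is a candidate explanation, while Mki67 did not pass (-0.12 ± 0.13). Of the 28 DNA replication and repair genes 19 fell and 1 rose, but 8 did not pass. Among these were Pcna (-0.26 ± 0.16), Mcm6 (-0.38 ± 0.21) and Mcm4 (-0.13 ± 0.14).

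Over windows of 51 neighbouring tested genes the highest absolute median log2 difference was 1.43, on chromosome 13 between 21715763 and 23764406, where 43 of 51 genes were histones, so a cluster of 1 gene family accounts for it. Without histone and clustered protocadherin genes the highest was 0.68, on chromosome 1 between 135231995 and 139178960 (GRCm38), with 21 genes higher and 3 lower and a shift of 0.77 and 0.65 within the 2 pairs of libraries (permutation p = 0.004). Of 15 overlapping windows beyond the 0.595 that 95% of 1000 shuffles stayed under, 11 were higher on chromosome 1 and 4 were lower on chromosome 5, between 96996206 and 105613018 (median -0.61). Whole chromosomes differed too: 6 of 20 had a median, relative to all genes, past an adjusted permutation p of 0.05. The 4 higher ones shifted little, namely chromosomes 1 (0.08), 3 (0.09), 7 (0.07) and 9 (0.10). The 2 lower ones were chromosome 12 (-0.19) and chromosome 16 (-0.17), both at an adjusted permutation p of 0.01. For windows and chromosomes alike, the shuffles treat genes as independent and do not measure the spread between libraries. Regional or copy number differences between the cell populations could produce such shifts, and RNA alone does not separate them from regulation of neighbouring genes.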
